A study of Drosophila melanogaster with 36 samples.

How the data were processed

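The arrays measured RNA of Drosophila melanogaster of the y cn bw sp strain on spotted probes for cytochrome P450s, glutathione S-transferases (GSTs), esterases and a few other genes. Per the labels, 3rd instar larvae were exposed for 4 h to caffeine, phenobarbital, diazinon, dicyclanil, lufenuron, spinosad or nitenpyram, and adult males to DDT or phenobarbital. For each of these 9 exposures, 8 samples of 50 exposed individuals and 8 of 50 control individuals were extracted, and each arm was pooled before labelling, which made 400 individuals per pool. Each pair of pools was hybridised on 4 two-colour arrays. The exposed pool carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4. The 4 arrays are therefore technical repeats of 1 pool pair, and an array-level test compares 2 RNA pools, not cultures or animals.

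The deposited table held log2 ratios of the 2 dyes for 1936 spots per array. Per the submitters' processing notes limma was used upstream, with no version and no role given. Background handling and normalization were not stated. The deposited values were not centred: the median over named genes ran from -1.95 to 0.63 on the log2 scale between arrays. A ceiling value equal to the log2 of 100000 stood in 2301 places and was taken as a code for a ratio without a usable denominator. It was treated as missing, as were 8543 empty values. Missing values made up 5.00% of the named-gene values and 21.1% of the values of unnamed spots. No signal intensities were used here, so the strength of signal over background was unknown, and the number of arrays limits the precision.

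The direction of the ratio (Cy5 over Cy3) was not stated in the labels. It was taken from limma's usual red over green convention, and with that direction Cyp6a2, Cyp6a8 and Cyp6a9, fixed beforehand as inducible genes from earlier literature, were higher in the phenobarbital pools. If the direction were turned, each higher and lower in the text would swap. Arrays of opposite dye orientation were correlated across genes after centring and after removal of each gene's mean over the arrays used. In the deposited direction the mean r was -0.90 in phenobarbital larvae, -0.62 in phenobarbital adults and -0.36 in caffeine larvae. It lay between 0.12 and 0.54 in the other 6 groups. There genes alone do not show whether ratios had already been turned to exposed over control. On all 34 arrays used, however, 246 of 668 unnamed spots changed sides with the dye of the exposed pool, so the ratios were taken as not turned in any group. Array 4 of DDT adult males and array 4 of phenobarbital adult males held identical values in 1936 of 1936 spots. They cannot both be right, and both were left out. Compared afterwards, their ratios resembled DDT more: across genes they correlated at r = 0.83 with the DDT array of the same dye orientation and at -0.07 with that of phenobarbital, and the centred log2 Cy5/Cy3 ratio of Cyp6a8, -4.76 on that phenobarbital array, was -0.95. The 34 arrays used comprised 4 for each of the 7 larval pool pairs and 3 for each of the 2 adult pool pairs. The label of DDT array 1 gave another holding time before exposure than the other adult labels.

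The table of probe genes gave 1 symbol for 656 spots, several for 8 and none for 1272. The 656 spots covered 159 genes, of which 158 were found in the reference by their gene identifier and 155 had 4 spots. Cyp12d1 was not among them. Spots of a gene were averaged per array, and 156 to 159 genes had a value on each array. The median over arrays of the SD between the spots of a gene was 0.57 on the log2 scale. Each array was centred on the median of its named genes. The plan fixed before the data were examined had assumed normalised values. Centring was therefore made the default once the values were seen, and the values as deposited became an alternative.

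Ratios were turned to exposed over control, and limma 3.58.1 in R 4.3.3 fitted 1 coefficient per compound and stage plus a dye term common to all arrays, with a pooled estimate of array error. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05 within the compound and its ratio was at least 1.5-fold either way. Phenobarbital in larvae and in adults was compared by a contrast in the same fit. Tests at the level of exposures used the 7 larval pool pairs as replicates, each the average of its arrays, again with limma at an adjusted p under 0.05: their mean against 0, the 5 insecticides against caffeine and phenobarbital, and each compound against the other 6. There the lone compound was assumed to vary like the others. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The fits were tested on simulated data.

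Gene lists were fixed before the data were examined: cytochrome P450s, GSTs, esterases, the CYP3, CYP4, mitochondrial and CYP2 clans of P450s, the Cyp6a subfamily, delta, epsilon and other GSTs, the alpha-esterase cluster, ecdysteroid synthesis genes, prior-literature genes (Cyp6a2, Cyp6a8, Cyp6a9, Cyp6g1, GstD1 and GstD2), male reproductive tract esterases, the oenocyte marker Cyp4g1, and all other genes. For each compound the list median was placed among 10000 random lists of its size. Over the 7 larval pool pairs, 15 lists with at least 3 genes were tested by an exact sign-flip permutation test and by an exact permutation over the 21 splits into 5 and 2 pool pairs, both two-sided, with adjustment over the lists. The smallest p values these designs allow were 0.0156 and 0.0476.

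Genes named in the text were chosen by a rule written beforehand. For a compound they were up to 20 called genes with the largest ratio and the same direction on all its arrays, with the prior-literature genes always added. For other comparisons they were up to 10 called genes with the largest effect. Some genes are named beyond the rule, and not all of them are marked where they stand. GstE12, GstE13, alpha-Est6, GstS1, Hsp26 and Hsp27 are among those not marked. Alternatives covered the centring and scaling of the arrays, the summary of spots, filters on missing values, the dye term, the replicate block, separate fits, the size threshold, the identical adult arrays and the removal of single arrays or compounds.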

Results

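RNA of Drosophila melanogaster exposed for 4 h to 8 compounds was compared with that of unexposed controls for 159 named genes. By their symbols these comprised 85 cytochrome P450s, 34 glutathione S-transferases (GSTs), 16 esterases and 24 other genes. The esterases so listed include Nlg1, Nlg3 and Nlg4. The other genes may hold further esterases, such as CG4757 and gas, so the counts are those of symbol lists. The 7 larval groups were caffeine at 1.5 mg/ml, phenobarbital at 10 mM, diazinon at 0.013%, dicyclanil at 0.067%, lufenuron at 20 ppm, spinosad at 6e-05% and nitenpyram at 6 ppm. The 2 adult male groups were DDT at 10 µg per vial and phenobarbital, given as 10 µl of a 1 M solution per vial. Both were given with 150 µl acetone per vial. Each group had 4 arrays of 1 pool pair, of which 3 were used in adults. Between 1504 and 1732 spots gave a ratio on each array. Values are log2 ratios of exposed over control ± SE, with n = 4 arrays in larvae, except where 3 are stated, and n = 3 in adults. Because an array has no value for total RNA, each ratio is relative to the median of the named genes on that array.

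The first question, posed by the title of the series, was whether the compounds induced known detoxification families. In larvae given phenobarbital, a barbiturate used as a general inducer of P450s, the highest ratio was that of GstD2, at 4.66 ± 0.19 or 25.3-fold over control. Cyp6a21 rose 20.6-fold (4.37 ± 0.18), Cyp4d14 14.4-fold (3.84 ± 0.20), Cyp6w1 14.1-fold (3.82 ± 0.16) and Cyp6d5 13.2-fold (3.72 ± 0.17). Cyp6a9 rose by 3.59 ± 0.20, Cyp28a5 by 3.38 ± 0.15 and Cyp6d4 by 2.92 ± 0.16. Hsp22, which encodes a small mitochondrial heat shock protein, rose 4.02-fold (2.01 ± 0.22). The largest falls were in Cyp311a1 (-2.05 ± 0.17) and Cyp310a1 (-1.96 ± 0.23).

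Of the 85 P450s, 25 rose and 8 fell in phenobarbital larvae, 33 in all, and 33 passed when adjusted over the list alone. The rises lay mostly in the CYP3 clan, with 15 of 38 members higher and 1 lower (16 adjusted over the list alone). Its Cyp6a subfamily had 8 of 14 higher and 0 lower (8 adjusted over the list alone), among them Cyp6a2 (2.15 ± 0.36) and Cyp6a8 (1.94 ± 0.28). The CYP4 clan went both ways, with 6 of 32 higher and 5 lower (10 adjusted over the list alone). Its higher members included Cyp4e3 (2.18 ± 0.16), Cyp4e2 (2.08 ± 0.17) and Cyp4ae1 (2.08 ± 0.21). In the mitochondrial clan 4 of 9 rose, led by Cyp12a5 (2.27 ± 0.34), and 0 fell (4 adjusted over the list alone). In the CYP2 clan 0 of 6 rose and 2 fell (2 adjusted over the list alone). Cyp9b1 rose by 2.24 ± 0.30. Cyp6g1, a P450 tied to DDT resistance when overexpressed, rose by 1.68 ± 0.22. In the list of prior-literature genes 5 of 6 rose (5 adjusted over the list alone), and GstD1 stood at 0.54 ± 0.21 and did not reach the size threshold. Cyp6a2, Cyp6a8 and Cyp6a9 of this list were also used to set the direction of the ratios, so its rise with phenobarbital is not independent evidence of direction.

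GSTs, which conjugate glutathione to electrophilic compounds, were called in both directions in phenobarbital larvae. In the delta class 7 of 11 rose and 1 fell (8 adjusted over the list alone), among them GstD7 (2.64 ± 0.42) and GstD5 (2.62 ± 0.22). In the epsilon class 1 of 11 rose, GstE3 (2.57 ± 0.21), and 5 fell (6 adjusted over the list alone), of which GstE12 and GstE13 stayed called with arrays centred on all spots and none as deposited or with arrays centred on control genes or the spike midpoint. The classes were not tested against each other. Among other GSTs 2 of 12 rose and 2 fell (4 adjusted over the list alone), so the whole family had 10 higher and 8 lower of 34 (18 adjusted over the list alone). Of the 16 esterases 0 rose and 5 fell (4 adjusted over the list alone), and of the 8 members of the alpha-esterase cluster 2 fell (2 adjusted over the list alone). Of 5 ecdysteroid synthesis genes 1 fell (1 adjusted over the list alone), and the oenocyte marker Cyp4g1, a P450 of hydrocarbon synthesis, stood at -0.95 ± 0.23 and also fell (1 adjusted over the list alone). Est-P, the 1 measured male reproductive tract esterase, was not called at -0.39 ± 0.50 (0 adjusted over the list alone). Of the 24 other genes 1 rose and 12 fell (13 adjusted over the list alone). These included genes often used as steady controls, chosen here after their values were seen: Gapdh1 (-0.89 ± 0.19), RpL10Aa (-0.67 ± 0.20), RpS20 (-0.67 ± 0.21) and RpS21 (-0.63 ± 0.16).

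By limma against array error, 69 of 159 genes were called in phenobarbital larvae, 36 higher and 33 lower. All 36 higher genes stayed called as deposited and with arrays centred on all spots, control genes or the spike midpoint, and 30 did with arrays scaled to the same spread. Those centrings raised all ratios together, the median of all genes from -0.15 to between 0.08 and 0.63, so higher calls could be lost there only through a larger spread. Of the 33 lower genes only Cyp310a1 and Cyp311a1 stayed called in all of those centrings. On all spots 13 of them did and on the spike midpoint 9, alpha-Est6 (-1.09 and -1.06) and Gapdh1 (-0.66 and -0.62) among both, but as deposited 2 and on control genes 3. As deposited, without centring, the split was 54 higher and 2 lower, and the list medians of the esterases (-0.47 centred, 0.31 as deposited), epsilon GSTs (-0.56 and 0.22) and other genes (-0.67 and 0.11) changed sign.

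**Figure D1:**
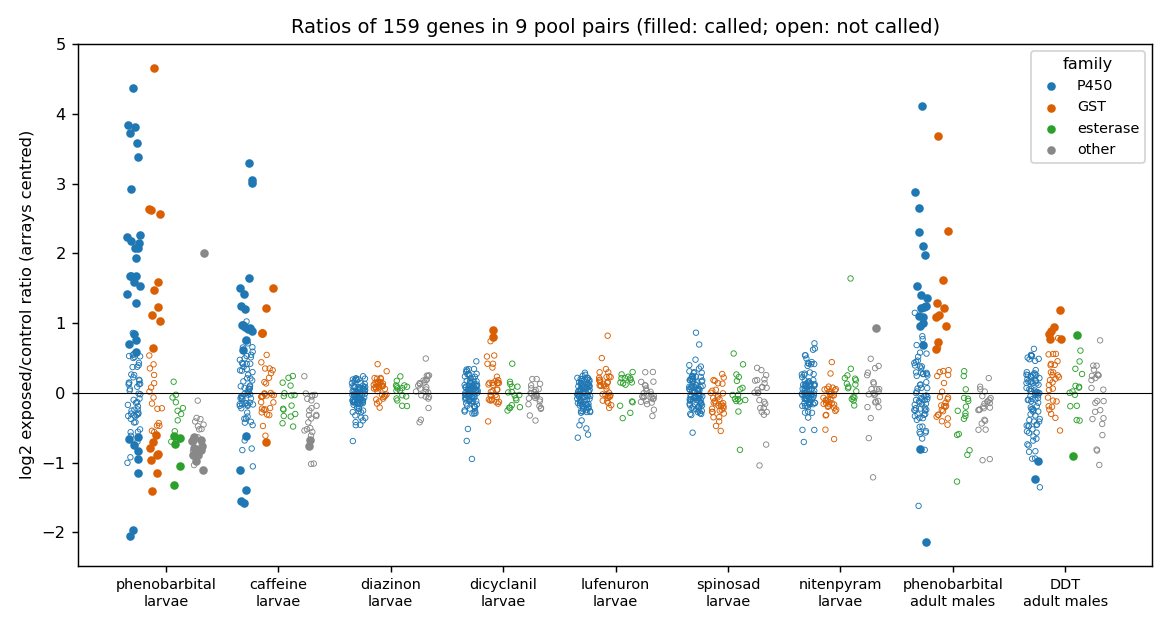
Each point is the log2 exposed/control ratio of 1 of the 159 genes in 1 of the 9 pool pairs, with arrays centred on the median of their named genes, filled where called by limma and coloured by gene family. Phenobarbital larvae had 69 filled points and caffeine larvae 28, and the 5 larval insecticides had 3 together.

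In larvae given caffeine, a methylxanthine, Cyp6d5 rose 9.84-fold (3.30 ± 0.17), Cyp6a8 8.28-fold (3.05 ± 0.28) and Cyp6w1 8.08-fold (3.01 ± 0.16). Further rises were those of Cyp6a21 (1.64 ± 0.18), Cyp6a2 (1.51 ± 0.36), GstE3 (1.50 ± 0.21), Cyp4ae1 (1.42 ± 0.21), Cyp6d4 (1.24 ± 0.16), GstE1 (1.22 ± 0.18) and Cyp12a5 (1.20 ± 0.34). Cyp6a9 rose by 0.98 ± 0.20, Cyp6g1 by 0.97 ± 0.22 and GstD2 by 0.86 ± 0.19, while GstD1 was not called at 0.15 ± 0.21. Cyp316a1 (-1.57 ± 0.31) and Cyp310a1 (-1.11 ± 0.23) were lower.

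Among the P450s 16 rose and 5 fell in caffeine larvae (21 adjusted over the list alone), with 10 of the rises in the CYP3 clan (12 adjusted over the list alone, 2 of them lower) and 5 in the Cyp6a subfamily (5 adjusted over the list alone). The CYP4 clan had 4 higher and 2 lower (6 adjusted over the list alone), the mitochondrial clan 2 higher (2 adjusted over the list alone) and the CYP2 clan 1 lower (0 adjusted over the list alone). Among the GSTs 4 rose and 1 fell (5 adjusted over the list alone): GstD2 in the delta class, GstE1 and GstE3 higher and GstE13 lower in the epsilon class, and GstO1. By limma 0 of 16 esterases were called (0 adjusted over the list alone). Over all genes 28 were called, 20 higher and 8 lower, with 46 at an unadjusted p under 0.05. The ratios from the 2 dye orientations correlated at r = 0.39 across genes, against 0.92 in phenobarbital larvae. Of the 20 higher genes 19 stayed called without centring, and of the 8 lower genes 0 did. Cyp316a1 stayed called lower on all spots (-1.33), control genes (-1.115) and the spike midpoint (-1.34), and Cyp310a1 on all spots (-0.86). These settings raised the ratios together, which favours higher calls and works against lower ones. With arrays centred on 4 control genes the count rose to 47, of which 46 were higher.

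The response to caffeine overlapped with that to phenobarbital in larvae. Cyp6d5, Cyp6w1, Cyp6a8, Cyp6a21 and 12 further genes were higher in both, 16 against 4.53 expected if the calls were independent. Another 5 genes were lower in both against 1.66 expected, and 1 was called in opposite directions. None of these 5 stayed called with caffeine as deposited, and with phenobarbital only Cyp310a1 and Cyp311a1 did in all centrings. The overlap of lower genes thus depends on the centring. Across the 159 genes, which are not independent replicates, the ratios of the 2 compounds correlated at r = 0.70 and rho = 0.66.

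The 5 larval insecticides gave 3 calls together by limma. In dicyclanil larvae GstE1 rose 1.88-fold (0.91 ± 0.18, adjusted p = 0.00379) and GstD3 1.74-fold (0.80 ± 0.18, adjusted p = 0.00922), both in the same direction on 4 of 4 arrays. In nitenpyram larvae RpS21, a ribosomal protein gene, rose 1.91-fold (0.93 ± 0.16, adjusted p = 0.000601), on 4 of 4 arrays. With diazinon, lufenuron and spinosad 0 genes were called by limma, with 2, 1 and 4 at an unadjusted p under 0.05. Dicyclanil had 8 and nitenpyram 9 at that level.

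Of the prior-literature genes 0 were called by limma in any of the 5 insecticides (0 adjusted over the list alone in each). The lowest of their ratios was that of Cyp6a2 with nitenpyram (-0.53 ± 0.36) and the highest that of GstD1 with dicyclanil (0.52 ± 0.21). GstD2 stood at 0.41 ± 0.19 with diazinon, 0.42 ± 0.19 with dicyclanil, 0.16 ± 0.19 with lufenuron, -0.09 ± 0.19 with spinosad and -0.24 ± 0.19 with nitenpyram. Cyp6a8 stood between -0.29 ± 0.28 with dicyclanil and 0.31 ± 0.28 with spinosad. Of the 85 P450s 0 were called with any of the 5 insecticides by limma, and GSTs passed with dicyclanil alone, where 3 of 34 did when adjusted over the list alone. Est-P passed when adjusted over its list of 1 gene with nitenpyram (1.64 ± 0.58, 3 arrays with values of 3.77, -0.91 and 2.06) and Cyp4g1 with lufenuron (-0.60 ± 0.23), neither over all genes.

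The SD of the log2 ratios over all genes was 0.18 with diazinon, 0.20 with lufenuron, 0.23 with dicyclanil, 0.25 with spinosad and 0.30 with nitenpyram, against 0.70 with caffeine and 1.24 with phenobarbital, where the median SE of a gene was 0.22. In simulated data 45.7% of 1.5-fold, 81.5% of 2-fold and 98.5% of 4-fold changes were recovered in the insecticide groups. There 70, 65 and 65 gene values were changed at these folds over the 5 groups, around a dye term common to all arrays. The 1.5-fold changes lay at the size threshold itself. Recovery with few changed genes, or with dye effects that differ between compounds, was not simulated and may be lower. The 3 calls depended on single arrays: dicyclanil gave 4 without array 1 and 0 without array 2 or array 4, and nitenpyram 2 without array 1 or array 3 and 0 without array 2. As deposited the 5 insecticides gave 0 calls together by limma, with arrays scaled to the same spread 21, with a dye term per compound 11, and with arrays centred on the spike midpoint 25, of which 22 were lower genes with lufenuron.

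**Figure D2:**
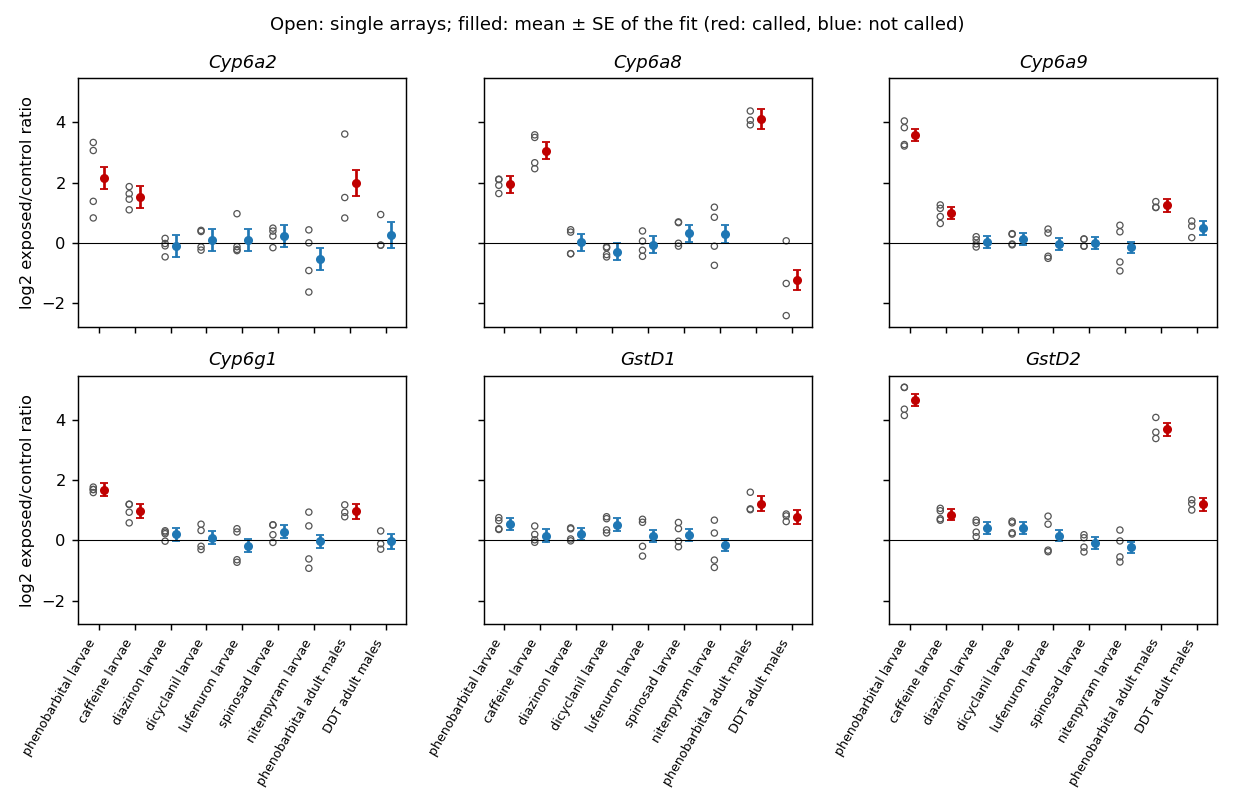
Open points are single arrays and filled points the mean ± SE of the fit, as log2 exposed/control ratios of the 6 prior-literature genes in each of the 9 pool pairs, in red where called. GstD2 reached 4.66 in phenobarbital larvae and 3.68 in phenobarbital adults, and stood between -0.24 and 0.42 in the 5 larval insecticides.

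The next comparison set exposures, not arrays, as replicates and asked whether the insecticides differed from caffeine and phenobarbital. Averaged over the 5 insecticide pool pairs, Cyp6d5 was lower than in the caffeine and phenobarbital pairs by a log2 difference of -3.55 ± 0.18 (adjusted p = 2.81e-06) and Cyp6w1 by -3.42 ± 0.22 (adjusted p = 1.09e-05). Cyp6a21 differed by -2.98 ± 0.58, GstD2 by -2.63 ± 0.80, Cyp6a8 by -2.44 ± 0.30, Cyp4d14 by -2.32 ± 0.64 and Cyp6a9 by -2.29 ± 0.55. Cyp6d4 (-2.05 ± 0.38), Cyp6a2 (-1.87 ± 0.25) and GstE3 (-1.82 ± 0.31) followed. For these 10 genes the insecticide means lay between -0.04 and 0.21.

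By limma with n = 5 against 2 pool pairs, 45 genes differed, 25 lower and 20 higher with the insecticides. All 25 lower genes stayed called with arrays as deposited, or centred on all spots, control genes or the spike midpoint, and 17 did with arrays scaled to the same spread. Of the 20 higher genes those settings kept 0, 6, 1, 2 and 2. As deposited 74 genes were lower and 0 higher with the insecticides, and on control genes 75 and 1. The gene median as deposited was 0.58 with caffeine and 0.78 with phenobarbital, against -0.54 to 0.18 with the insecticides. These 2 settings and the spike midpoint thus moved the differences down together. Lower calls were favoured there, so that they stayed called says little. The count ran from 25 without diazinon to 76 without caffeine, with 27 without lufenuron and 28 without spinosad.

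As groups, the P450s lay 0.50 above all other genes with caffeine and phenobarbital and -0.02 from them with the insecticides, a difference of -0.52 over n = 7 pool pairs (exact permutation p = 0.0476, the smallest the 21 splits allow, adjusted p = 0.0893). The same p and adjusted p held for the CYP3 clan (-0.75), the Cyp6a subfamily (-0.95), the prior-literature genes (-1.70), the esterases (0.53), the alpha-esterase cluster (0.50), the ecdysteroid synthesis genes (0.57) and the other genes (0.70). The exact permutation p was 0.19 for the delta GSTs (-0.53) and the CYP2 clan (0.27), 0.0952 for the mitochondrial clan (-0.25) and other GSTs (0.18), 0.143 for the CYP4 clan (0.07), 0.286 for the epsilon GSTs (0.20) and 0.762 for all GSTs (-0.05). With phenobarbital left out the differences of the delta GSTs (0.0009) and the CYP2 clan (-0.0009) vanished. Those of all GSTs (0.02) and the epsilon GSTs (-0.03) changed sign. The P450s (-0.38), the CYP3 clan (-0.54) and the esterases (0.28) kept theirs at a smaller size. None of the 15 lists passed after adjustment, which this design allows only if all 15 reach the smallest p.

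For a response common to the larval compounds, limma over the 7 pool pairs called 0 genes, with 15 at an unadjusted p under 0.05. The gene with the smallest p was phtm, of ecdysteroid synthesis, named after its values were seen (-0.64 ± 0.17, higher in 0 of 7, limma adjusted p = 0.475). The list shifts over the 7 pool pairs had adjusted p values from 0.312 to 0.516 by the exact sign-flip permutation test. Set against the other 6 larval compounds, phenobarbital differed in 52 genes by limma, 28 higher and 24 lower, with the spread of the lone phenobarbital pool pair not measured but assumed equal to that of the others. The largest differences were in GstD2 (4.41 ± 0.37), Cyp6a21 (4.07 ± 0.60), Cyp4d14 (3.73 ± 0.31), Cyp6a9 (3.43 ± 0.38), Cyp28a5 (3.32 ± 0.23) and Cyp6w1 (3.32 ± 1.06), followed by Cyp6d4 (2.69 ± 0.47), GstD7 (2.47 ± 0.39), GstD5 (2.46 ± 0.21) and Cyp9b1 (2.22 ± 0.35).

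Caffeine differed from the other 6 compounds in 0 genes by limma, with 11 at an unadjusted p under 0.05, and in 33 with phenobarbital left out. By the same test diazinon, dicyclanil, lufenuron, spinosad and nitenpyram each differed in 0 genes, with 0, 1, 1, 2 and 4 at an unadjusted p under 0.05. The 52 genes of phenobarbital became 31, all higher, as deposited, 16 with arrays scaled to the same spread and 31 with the spike midpoint, and ran from 43 without diazinon to 76 without caffeine.

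In adult males given phenobarbital, Cyp6a8 rose 17.4-fold (4.12 ± 0.33), GstD2 12.8-fold (3.68 ± 0.23), Cyp6a21 7.37-fold (2.88 ± 0.21) and Cyp6w1 6.27-fold (2.65 ± 0.19). GstE3 (2.32 ± 0.25), Cyp6d5 (2.31 ± 0.20), Cyp4ae1 (2.11 ± 0.24), Cyp6a2 (1.98 ± 0.42), GstD7 (1.62 ± 0.48), Cyp12c1 (1.54 ± 0.15) and Cyp4e2 (1.41 ± 0.20) also rose. GstD1 rose 2.33-fold (1.22 ± 0.24), GstE1 by 1.11 ± 0.21, Cyp6a9 by 1.24 ± 0.23 and Cyp6g1 by 0.96 ± 0.26. The gene phtm, whose product acts in ecdysteroid synthesis, was lower at -2.14 ± 0.64.

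In these adults 17 P450s rose and 2 fell (19 adjusted over the list alone), 9 of the rises being in the CYP3 clan (10 adjusted over the list alone, 1 of them lower), 4 in the Cyp6a subfamily (4 adjusted over the list alone), 6 in the CYP4 clan (6 adjusted over the list alone) and 2 in the mitochondrial clan (2 adjusted over the list alone). All 6 prior-literature genes rose (6 adjusted over the list alone). Of the 34 GSTs 10 rose and 0 fell (10 adjusted over the list alone), 6 in the delta class and 4 in the epsilon class. By limma 0 of 16 esterases were called (0 adjusted over the list alone), with Est-P at -1.27 ± 0.58, which passed when adjusted over its list of 1 gene. Over all genes 29 were called, 27 higher and 2 lower, with 41 at an unadjusted p under 0.05. All 27 higher genes stayed called in the other centrings and with arrays scaled to the same spread, and the 2 lower ones only with that scaling. Those centrings raised the ratios together, that of Cyp6a8 from 4.12 to between 4.35 and 4.78, which favours higher calls. The gene phtm stood between -1.915 and -1.48 there, and Cyp310a1 (-0.81 by default) between -0.58 and -0.15. The count was 44 with a dye term per compound and 46 in a separate fit.

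Phenobarbital was the compound given at both stages, with a different dose and route. Cyp28a5 had a larger ratio in larvae than in adults, by a log2 difference of 3.47 ± 0.23. So had Cyp6d4 (2.67 ± 0.25), Cyp4d14 (2.48 ± 0.31), Cyp9b1 (2.40 ± 0.46), Cyp6a9 (2.35 ± 0.30), Hsp22 (2.05 ± 0.34) and Cyp12a5 (1.89 ± 0.52). In adults Cyp28a5, Cyp9b1 and Hsp22 stood at -0.09, -0.16 and -0.05 relative to the array median and were not called. The other centrings raised the adult ratios together, so these values would stand higher there. Cyp6a8 differed in the other direction, at -2.18 ± 0.43, as did GstE8 (-1.78 ± 0.27), at -0.70 in larvae and 1.09 in adults, and Cyp311a1 (-1.75 ± 0.26). GstD2, Cyp6a21, Cyp6w1 and Cyp6d5 were high at both stages, and 22 genes were called higher in both against 6.11 expected.

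By limma 28 of 159 genes differed between the stages, 18 with the larger ratio in larvae and 10 in adults, against array error of 1 pool pair per stage. Of these 10, only Cyp6a8, GstE5 and GstE8 were called higher in adults. The rest were called lower in larvae and were not called higher in adults. As deposited 10 differed and with a dye term per compound 52. Centring on the spike midpoint turned the split to 15 and 21, scaling to the same spread gave 9 and 13, and centring on control genes gave 31 and 5.

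**Figure D3:**
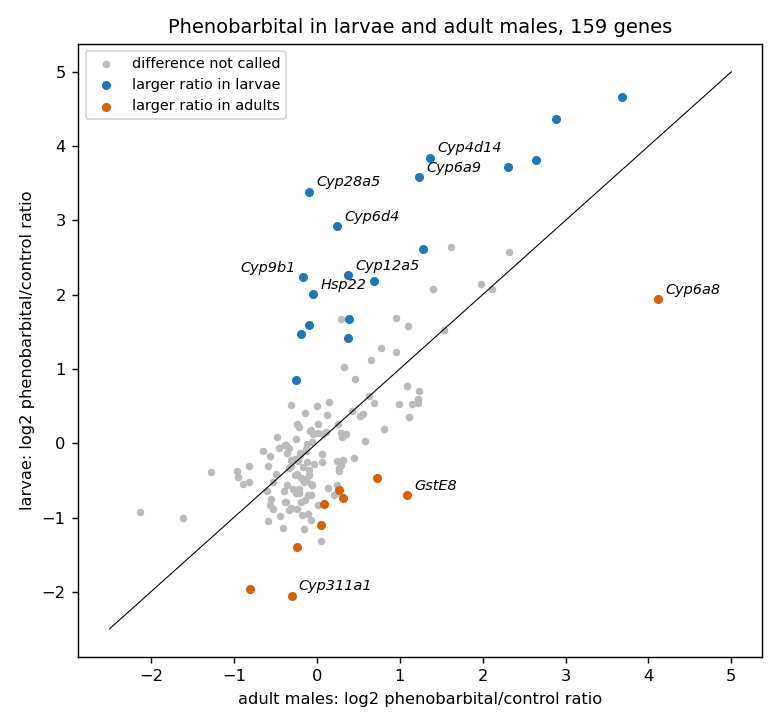
Each point is 1 of the 159 genes, with its log2 phenobarbital/control ratio in adult males on the x axis and in larvae on the y axis, and the line marks equal ratios. The 18 genes with a larger ratio in larvae and the 10 with a larger ratio in adults are coloured, and the 10 largest differences are named.

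In adult males given DDT, an organochlorine, the higher genes were mostly GSTs. GstD2 rose 2.28-fold (1.19 ± 0.23, adjusted p = 0.00207 by limma), GstD5 by 0.95 ± 0.26, GstD8 by 0.89 ± 0.27, GstT4 by 0.84 ± 0.24, and GstE1 and GstD1 by 0.77 ± 0.21 and 0.77 ± 0.24. Ace, which encodes acetylcholinesterase, rose by 0.83 ± 0.24. Cyp4ac1 (-0.98 ± 0.24) and alpha-Est2 (-0.90 ± 0.19) were lower on 3 of 3 arrays. Cyp6a8 was lower at -1.23 ± 0.33 but differed between arrays, with single values of -2.42, 0.07 and -1.35, and with the left-out array 4 added was not called (-0.78, adjusted p = 0.131), nor was GstD1 (0.65, adjusted p = 0.0540). Cyp6a2 (0.26 ± 0.42), Cyp6a9 (0.48 ± 0.23) and Cyp6g1 (-0.03 ± 0.26) were not called.

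Of the 34 GSTs 6 rose and 0 fell with DDT (7 adjusted over the list alone), 4 of them among the 11 delta GSTs (4 adjusted over the list alone), whose median was at 0.45. Of the 85 P450s 0 rose and 2 fell by limma (2 adjusted over the list alone), and of the 16 esterases 1 rose and 1 fell (2 adjusted over the list alone). Over all genes 10 were called, 7 higher and 3 lower, with 29 at an unadjusted p under 0.05. With 2 arrays of the exposed pool in Cy5 and 1 in Cy3, the ratios from the 2 dye orientations correlated at -0.14 across genes. The 6 GSTs were higher on 3 of 3 arrays after removal of the common dye term, which was 0.61 for GstD1, 0.52 for GstE1, 0.46 for GstD5, 0.43 for GstD2, 0.35 for GstT4 and -0.03 for GstD8. The count moved with each array: 3 without array 1, 3 without array 3 and 17 (9 higher, 8 lower) without array 2. It was 20 (10 higher, 10 lower) with a dye term per compound, 4 with the array number as a block, 0 as deposited and in a separate fit by limma, 3 with the spike midpoint and 1 with arrays scaled to the same spread.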

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

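The tests of the dye orientations in phenobarbital larvae and of the spike-like spots were chosen after the results they measure were seen, and the tests of the higher and lower calls and of hidden insecticide changes rest on settings chosen after seeing the data: control genes, the spike midpoint and a dye term per compound.

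Phenobarbital gave different ratios in larvae and in adult males. The test of the difference itself called 28 genes. Larvae had the larger ratio in Cyp28a5 (3.47 on the log2 scale), Cyp6d4 (2.67), Cyp4d14 (2.48), Cyp9b1 (2.40), Cyp6a9 (2.35), Hsp22 (2.05) and Cyp12a5 (1.89), and adults in Cyp6a8 (-2.18), GstE8 (-1.78) and Cyp311a1 (-1.75). Of the 35 splits of the 7 phenobarbital arrays into 4 and 3, only the real 1 gave as many genes, 28 against 26 in the highest other split. The 7 arrays repeat 1 pool pair per stage, so these splits bear on array error alone and do not exclude chance between pool pairs. Stage, dose, route and control went together, so no biological explanation was tested.

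In phenobarbital larvae 36 genes such as GstD2, Cyp6a21 and Cyp6w1 were higher and 33 such as GstS1 and Gapdh1 lower. Centring on the named genes did not make the higher calls: as deposited, on control genes and on the spike midpoint the median of all genes stood higher (0.63, 0.56 and 0.11 against -0.15), so it had lowered these ratios, and all 36 stayed called. Dye bias does not account for the pattern of this group as a whole, whose ratios from the Cy5-exposed and the Cy3-exposed arrays correlated at r = 0.923 across genes. An r over all genes rests mostly on the large ratios. It does not decide for calls near the size threshold, such as Cyp4d8 (0.59, with a dye term of -0.93). For the lower genes centring may account for most, as 9 of 33 stayed called on the spike midpoint, and Cyp310a1 and Cyp311a1 were among them. A response to phenobarbital may lie behind the 36 higher genes, as a hypothesis from 1 pool pair against its own control.

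The 5 larval insecticides gave 3 calls, GstE1 and GstD3 with dicyclanil and RpS21 with nitenpyram. Smaller ratios on those arrays stay open: the range between the highest and lowest spike-like spots was 97.8% of that of the caffeine and phenobarbital larval pairs, and lower with nitenpyram (5.05 against 6.24 on the log2 scale), but what these spots hold is an assumption. Dye effects that differ between compounds may have hidden changes, as a dye term per compound gave 11 calls and the ratios from the 2 dye orientations correlated between -0.66 and -0.17 in the 5 groups. The 3 balanced assignments of 4 arrays are too few for a share under 0.05, and the real 1 gave 3 calls and the highest other 0. Insensitivity to the compounds at these doses was not tested apart from this.

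Diazinon larvae and DDT adult males, both exposed to insecticides, had ratios that correlated across genes at r = 0.44. With diazinon 0 genes were called by limma (2 at an unadjusted p under 0.05). That r was the highest among pairs of insecticide groups. DDT correlated at 0.31 with dicyclanil, -0.07 with lufenuron, -0.03 with spinosad and -0.16 with nitenpyram. Diazinon correlated at 0.13 with dicyclanil, -0.07 with lufenuron, 0.02 with spinosad and -0.08 with nitenpyram. A dye effect common to the diazinon and DDT arrays is excluded, since those of opposite dye orientation correlated at a mean r of 0.287 and those of the same orientation at -0.05. That difference leaves open dye effects of opposite sign in the 2 sets, which may have raised the 0.287. With both orientations weighted equally, where additive dye effects of either sign cancel, r was 0.45, and a similar response stays a hypothesis that 1 pool pair of each cannot test.

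In the comparison of the insecticides with caffeine and phenobarbital, led by Cyp6d5 and Cyp6w1, 1 of 21 splits gave as many genes. This was the real 1, with 45 genes against 0 in the highest other split of the 7 compounds. Its share of 0.0476 is the smallest that 21 splits allow. Phenobarbital and caffeine had the most calls in larvae, 69 and 28. Each other split put at least 1 of them among the 5, which widened the spread there. The splits therefore do not exclude chance between single pool pairs. For a response common to the 7 larval compounds the real pattern and the highest other both gave 0 genes by limma (15 at an unadjusted p under 0.05), so that 64 of 64 sign patterns gave as many by construction, which decides nothing.

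Cyp6a2 in lufenuron larvae had 1 array far from the others: array 2 stood at 0.97 on the log2 scale against a mean of -0.20 over the rest, a gap of 0.893 of the whole range. It was 1 of 91 groups of 4 arrays tested, where chance gives about 5%.

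Among 668 unnamed spots with a value on each array used, 246 followed the exposed pool, in that each array with the exposed pool in Cy5 lay on the same side of each array with it in Cy3. Of these 118 were higher in the exposed pool, with a median log2 ratio of 2.61, and the rest lower, with a median of -1.91. None of 382 named spots did so in either direction. These spots have no gene symbol, and the labels do not say what they hold.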

How the results depend on the processing

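The centrings on control genes and on the spike midpoint, the dye term per compound, the removal of genes with a missing spot, the identical adult arrays and the wider esterase list were chosen after seeing the data. The spike midpoint took the 32 highest and 32 lowest unnamed spots that follow the exposed pool as reciprocal spike mixes, an assumption. Directions were compared for the genes named by the rule and for the list tests, and none that was called reversed in any alternative. Some other genes changed sign. CG17806 (-0.69), GstE9 (-0.60) and RpS21 (-0.63), called lower in phenobarbital larvae, stood at 0.09, 0.18 and 0.15 as deposited, where they were not called. Of 2609 values of the genes named by the rule in alternatives 2423 kept their call, 176 lost it and 10 gained it. Sign changes of 58 gene values and 5 list shifts where neither setting gave a call were counted as unchanged. Of 472 alternatives of the list tests over compounds, 105 split tests with 1 compound left out could not pass, as their smallest p was 0.0667 or 0.167, and none of the other 367 passed. Centring moved the median of all genes in phenobarbital larvae from -0.15 to 0.63 as deposited, 0.08 on all spots, 0.56 on control genes and 0.11 on the spike midpoint. Signal over background was not available. Except where stated, the cause of a change was not tested.

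Arrays scaled to the same spread gave 39 genes in phenobarbital larvae, 11 with dicyclanil, 7 with lufenuron, 3 with spinosad, 0 with nitenpyram, 1 with DDT, 20 for insecticides against caffeine and phenobarbital and 16 for phenobarbital against the other larval compounds. List shifts per compound, each the list median minus the median of all genes, also moved with that scaling. In phenobarbital larvae these shifts became 0.43 for the CYP3 clan, 0.95 for the Cyp6a subfamily and 0.74 for delta GSTs. They became -0.36 for ecdysteroid synthesis, 1.42 for prior-literature genes and -0.35 for other genes. The shift was 0.78 for prior-literature genes with caffeine, 0.0055 for the mitochondrial clan in phenobarbital adults and 0.11 for GSTs with DDT. As deposited the counts were 0 with dicyclanil, nitenpyram and DDT by limma, 10 between the stages, 74 for insecticides against caffeine and phenobarbital and 31 for phenobarbital against the others. Centring on all spots gave 1 gene with spinosad and 0 with nitenpyram. Control genes gave 47 with caffeine, 2 with nitenpyram and 76 for insecticides against caffeine and phenobarbital. The spike midpoint gave 22 with lufenuron, 0 with nitenpyram, 3 with DDT and 31 for phenobarbital against the others.

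Genes with no missing spot, 56 in number, so that fewer were tested, gave 32 in phenobarbital larvae, 16 with caffeine, 1 with spinosad, 0 with nitenpyram, 16 in phenobarbital adults, 19 for insecticides against caffeine and phenobarbital and 27 for phenobarbital against the others. The 151 genes with a value on all arrays gave 1 with spinosad. In phenobarbital larvae they gave list shifts per compound of -0.12 for the alpha-esterase cluster and -0.29 for ecdysteroid synthesis. Medians of spots gave 1 with spinosad and 1 lower gene in place of RpS21 with nitenpyram. Their list shifts per compound were 1.09 for prior-literature genes with caffeine and 0.67 for the Cyp6a subfamily in phenobarbital adults. With DDT they were 0.27 for GSTs and 0.36 for epsilon GSTs.

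No dye term gave 18 with caffeine and 0 with dicyclanil, nitenpyram and DDT. A dye term per stage gave 1 with spinosad. A dye term per compound gave 4 with dicyclanil, 2 with lufenuron, 2 with spinosad, 3 with nitenpyram, 44 in phenobarbital adults, 20 with DDT and 52 between the stages. A separate fit gave 1 with spinosad, 0 with nitenpyram, 46 in phenobarbital adults and 0 with DDT. A 2-fold threshold, stricter by construction, gave 39 in phenobarbital larvae, 14 with caffeine, 0 with dicyclanil and nitenpyram and 2 with DDT.

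Array numbers do not pair the compounds: arrays of the same number correlated at a mean r of -0.07 and others of the same dye at -0.09. The full block of 4 array numbers could not be fitted beside the exposures, as 1 of its contrasts equals the exposure itself, so after its first run the block held the dye term and the contrasts within each dye. That block gave 4 genes with DDT, 68 in phenobarbital larvae, 28 with caffeine, 28 in phenobarbital adults and 29 between the stages.

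Leaving out 1 array gave 60 to 63 genes in phenobarbital larvae, 24 to 31 with caffeine, 0 to 4 with dicyclanil, 0 to 2 with nitenpyram, 21 to 34 in phenobarbital adults, 3 to 17 with DDT and 25 to 32 between the stages. Leaving out 1 compound gave 25 to 76 genes for insecticides against caffeine and phenobarbital, 43 to 76 for phenobarbital and 0 to 33 for caffeine against the others. The identical array kept in a group gave 21 genes in phenobarbital adults, 9 with DDT and 33 between the stages.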

Other observations

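The test of neighbouring genes below was chosen before its result was seen. In spinosad larvae CG4757 had the lowest ratio, at -1.04 ± 0.26 with an adjusted p of 0.055 by limma, chosen here after its value was seen. Est-P in nitenpyram larvae, at 1.64 ± 0.58 in the fit of 3 arrays, was 1.00 when both dye orientations were weighted equally, and was not called. In lufenuron larvae GstD7 had the highest ratio, at 0.82 ± 0.42, also not called. Cyp18a1, the ecdysteroid 26-hydroxylase, stood at 0.86 ± 0.37 with phenobarbital in larvae and was not called. With caffeine it had a value on 3 arrays, which ranged from -0.94 to 3.61, with 1.02 ± 0.43 in the fit and 1.67 when both dye orientations were weighted equally. Hsp26 fell with caffeine (-0.76 ± 0.13), and Hsp27 with phenobarbital in larvae (-0.80 ± 0.16), both relative to the array median. Neither stayed called in the other centrings, and as deposited they stood at -0.18 and -0.02.

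Many P450 and GST genes lie in clusters on the chromosomes, so a hypothesis was that adjacent genes of a family responded alike to phenobarbital in larvae. Over 48 adjacent pairs among 132 genes, 73.0% of 10000 permutations of values within families gave a mean absolute difference as small. For the size of the log2 ratio this does not bear the hypothesis out. Whether adjacent genes shared a direction was not tested.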
